A study of Homo sapiens with 9 samples.

How the data were processed

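RNA was measured by sequencing in 9 libraries from LC-2/ad, an established human lung adenocarcinoma line that carries a CCDC6-RET gene fusion, and from the ponatinib-resistant derivatives PR1 and PR2. Ponatinib is a multi-kinase inhibitor whose targets include RET. Each group had 3 libraries, lettered A, B and C. Per the labels, PR1 and PR2 were cultured in 200 nM ponatinib. No drug is stated for the parental cells, so resistance and the presence of the drug could not be separated in any comparison with them. The labels do not say whether the letters stand for separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

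Per the labels' protocols, RNA was isolated with a column kit and libraries were made with a TruSeq RNA kit. The submitters' processing notes name TopHat2 2.0.14, Cufflinks 2.2.1 and Cuffdiff 2.2.1 and the builds GRCh37 and hg19. The gene annotation and the number of reads per library are not given in the sources used here. The deposited table holds FPKM values (fragments scaled to transcript length and to the mapped fragments of the library) for 24069 rows in 9 columns, 1 per library. The unit is an inference. The header names none, but Cufflinks reports FPKM, the columns sum to between 571570 and 686460, and the smallest steps between values scale with gene length. Among the rows, 704 are loci in which the authors' values combine several genes, written with commas (HLA-B,HLA-C), and their values cannot be split between the genes.

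FPKM values keep no absolute depth. Single-fragment steps of low genes gave relative depths of 0.761 to 1 against parental A, the deepest library, so depth differed little between the groups. Values were 0 in every library for 5378 rows. TUBB, BRD2, FLOT1, DDR1, TAPBP and HLA-E, which most cells express, were among them, so a 0 in this table can be a failed estimate. A gene at 0 is therefore described as listed at 0, with the value of each library and no fold change.

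Expression was analysed as log2(FPKM + 1) in R 4.3.3. Rows at 1 FPKM or more in at least 3 of the 9 libraries were tested, which left 12011 rows, of which 561 were combined loci. Groups were compared with limma 3.58.1, fitting 1 mean per group to all 9 libraries with an intensity trend in the empirical Bayes step. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method. Changed genes had an adjusted p under 0.05, and those with a log2 fold change of 1 or more in size were also counted. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Errors are SDs over 3 libraries for FPKM values and standard errors for log2 fold changes.

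Before the data were examined, 32 gene lists with 681 entries were fixed. They covered receptor kinases and their ligands, MAPK signalling, lineage and epithelial or mesenchymal state, markers of fibroblasts, blood cells and neuroendocrine cells, drug handling, stress, metabolism and growth control. Entries that fell in combined loci (35) or matched no row (2) were left out. Lists with at least 4 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. List p-values were adjusted over all lists and the 3 comparisons. Members were counted over all genes tested and adjusted over the list alone.

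The genes named in the report followed a rule fixed before the data were examined. In each comparison it took the 6 genes with the largest rise and the 6 with the largest fall among changed genes whose groups did not overlap and whose higher group had a mean of at least 5 FPKM, leaving out symbols of the LOC, LINC, MIR, SNOR, RNU and RNA5 kinds and antisense symbols. The rule read symbols only, so the pseudogene CYP2B7P stayed in. For 3 libraries against 3, chance alone keeps 10% of genes from overlapping. In the comparisons with parental cells it added the member of each list with the largest rise and with the largest fall of 2-fold or more, and in all comparisons a fixed set that included RET, CCDC6, AXL, EGFR, MET and HRAS. Some genes that the rule named are not reported here. Up to 5 further members of each list that passed camera, taken by the size of their change, were added after the data were seen, as were the genes of the closing observations.

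The letters were checked for pairing through the correlation, across genes, of deviations from the group means. Libraries with the same letter correlated in PR1 and parental cells (A 0.31, B 0.48, C 0.16) and in PR2 and PR1 (A 0.53, B 0.54, C 0.25), so the letters paired the libraries of those comparisons. The fit with the letter as a block is given where it changed a result. In PR2 and parental cells the A and B libraries correlated as well (0.30 and 0.42). The C libraries did not (0.014), so the letters were not taken as pairs there. Each letter held 1 library of each group, so a comparison within a single letter has no replicates.

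Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-of-ratios scaling, quantile normalization, no trend, a robust fit, only the 6 libraries compared, the letter as a block, a test against a 2-fold change (treat), and leaving out each library in turn. A fit without the 3 A libraries was added after the data were seen. The overlap of PR1 and PR2 changes was set beside 100 simulations of unchanged groups against shared controls. The methods were tested on simulated data of 12011 genes with known changes. For PR1 against parental, 66 of 100 genes changed by a log2 of 1 and 98 of 100 changed by a log2 of 2 were recovered, and 13 unchanged genes were called. For PR2 against parental these numbers were 67, 99 and 8. Unchanged genes made up 7.34% and 4.60% of the calls. The simulated noise was independent between libraries and few genes were changed, unlike the real data, so these numbers do not measure the errors of the real fits. Transcript length and GC content came from a reference annotation matched by gene symbol. Figures were drawn with matplotlib. Genome positions are not given, since the reference used for names differs from the build in the submitters' notes.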

Results

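The 9 libraries came from parental LC-2/ad cells, which carry a CCDC6-RET fusion, and from the derivatives PR1 and PR2 grown in 200 nM ponatinib, with 3 libraries per group. The libraries held between 11263 and 11629 genes at 1 FPKM or more, and the 10 highest genes took 7.54% to 11.2% of the summed FPKM. Across genes, log2(FPKM + 1) correlated at 0.961 to 0.985 between libraries of a group and at 0.883 to 0.949 between groups. No libraries were identical. The first principal component (41.9% of the variance) ran from parental through PR1 to PR2, and the second (25.8%) set PR1 apart. The third (12.6%) separated the A from the B libraries of every group, and parental A lay closer to the derivatives on the first component than parental B and C did. The counts of changed genes and of their overlap are therefore also given without the 3 A libraries, a choice made after the data were seen.

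**Figure D1:**
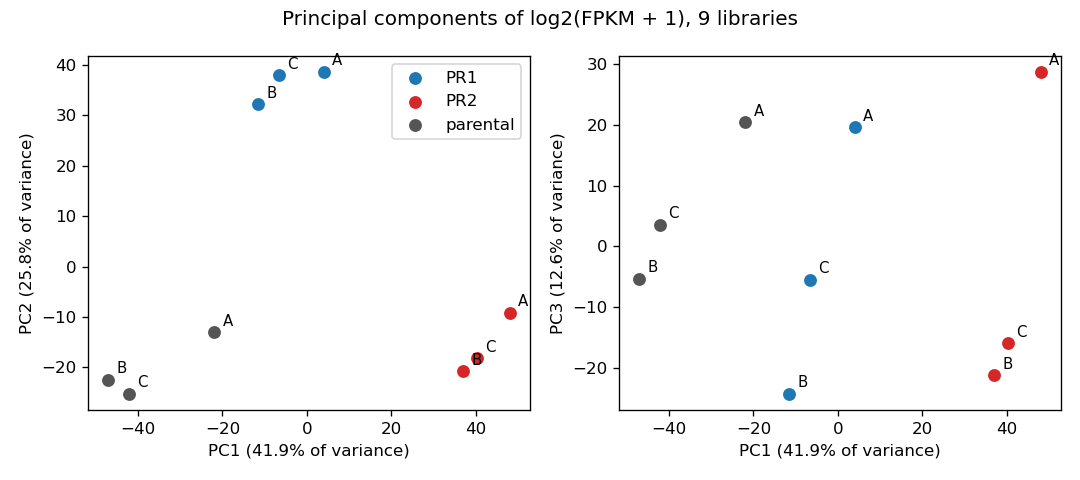
Principal components of log2(FPKM + 1) in the 9 libraries, coloured by group and lettered by replicate, with the first component (41.9% of the variance) on the x axis and the second (25.8%) or the third (12.6%) on the y axis. The groups separate on the first 2 components, and the A libraries lie at the top of the third.

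The receptor genes fixed beforehand were compared first, since LC-2/ad cells carry a RET fusion. AXL, a receptor tyrosine kinase, stood at 1.61 ± 1.51 FPKM in parental cells (SD, n = 3), 38.8 ± 13.4 in PR1 and 81.5 ± 21.2 in PR2. Its log2 fold change was 4.02 ± 0.37 (SE) in PR1 and 5.10 ± 0.37 in PR2 (limma adjusted p = 0.00012 and 1.4e-05). The AXL difference of 1.08 between PR2 and PR1 missed the threshold (limma adjusted p = 0.067) but passed it with the letter as a block and without the A libraries (limma adjusted p = 0.0025 and 0.0040). EGFR rose from 8.28 ± 1.34 FPKM to 15.7 ± 1.28 in PR1 and 23.4 ± 4.35 in PR2, by a log2 of 0.86 and 1.39 (limma adjusted p = 0.0088 and 0.00037). The EGFR difference of 0.53 between the derivatives missed it as well (limma adjusted p = 0.054) and passed with the block (limma adjusted p = 0.0092). RET was at 14.6 ± 1.31 FPKM in parental cells and 16.6 ± 0.61 in PR1, a log2 difference of 0.18 (limma adjusted p = 0.42), and fell to 8.50 ± 0.73 in PR2 (log2 fold change −0.71 against parental and −0.89 against PR1, limma adjusted p = 0.0040 and 0.0015). The RET values cover every transcript assigned to that gene, and the fusion was not measured separately. MET and CCDC6 passed the threshold in no comparison, with limma adjusted p of 0.87 for MET and 0.60 for CCDC6 in PR2 against parental cells. HRAS missed it too, with a log2 difference of −0.81 between PR2 and parental cells and −0.71 between PR2 and PR1 (limma adjusted p = 0.096 and 0.15). Both passed without the A libraries (−1.10 and −0.84, limma adjusted p = 0.0022 and 0.0094). With the block both passed too (limma adjusted p = 0.011 and 0.022), although the letters were not taken as pairs in PR2 against parental cells.

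**Figure D2:**
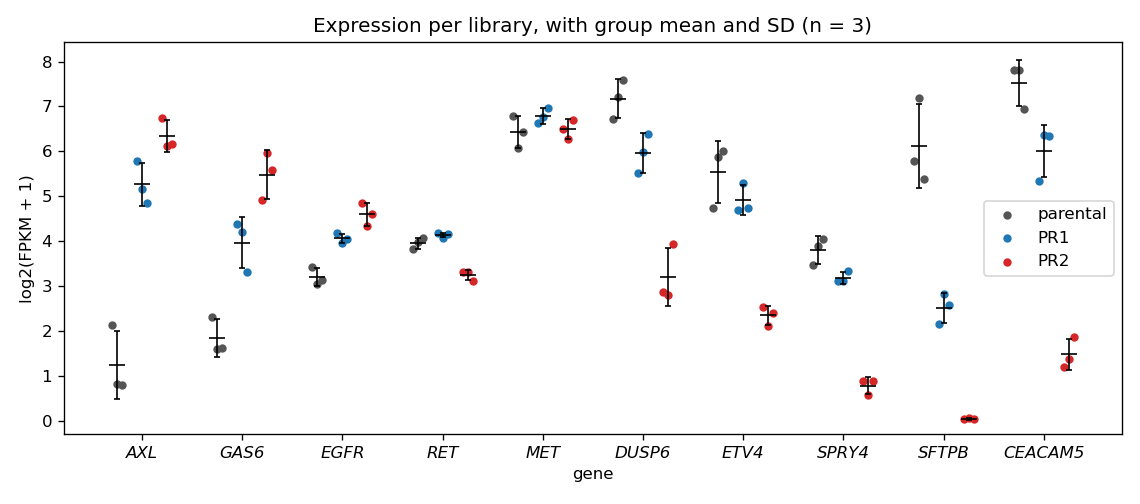
log2(FPKM + 1) of 10 genes (x axis) in the 3 libraries of each group, with points for libraries and bars for the mean and SD (n = 3). AXL is higher in both derivatives than in parental cells (38.8 and 81.5 against 1.61 FPKM), while DUSP6, ETV4 and SPRY4 are lowest in PR2.

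PR1 against parental cells asks what distinguishes the first derivative from the line it came from. In PR1 the LIM-domain gene CRIP1 rose from 10.1 ± 4.06 to 447 ± 186 FPKM (SD, n = 3), a log2 fold change of 5.32 ± 0.32. AXL, CRIP2, the growth factor gene BMP4, the actin-bundling gene FSCN1 and SDPR followed, with log2 fold changes from 4.02 down to 3.27. The falls were led by the secreted airway genes BPIFB1 (log2 fold change −5.62) and BPIFA1 (−4.73), CYP2B7P (−5.16), the combined kallikrein locus KLK11,KLK12 (−5.13), CAPN13 (−4.89), and CD74, the invariant chain of MHC class II, which dropped from 248 ± 38.5 to 7.22 ± 3.83 FPKM (−5.05). CYP2B7P is a pseudogene, and its reads can be shared with close copies. In all, 1866 of 12011 genes changed, 908 higher and 958 lower, and 801 changed at least 2-fold, 364 higher and 437 lower.

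Of 23 measured YAP and TEAD targets, genes induced by the Hippo pathway's transcription factors, 12 rose and 2 fell in PR1 (camera adjusted p = 2.3e-05, 0.62 with an estimated correlation), and 18 were past the threshold when adjusted over the list alone. AXL, ANKRD1 (log2 fold change 2.85), CYR61 (2.44) and NT5E (2.29) led the rises, and FOXF2 (−1.05) fell. CTGF rose by 2.75, a call lost without parental B, PR1 A or PR1 C, where the highest limma adjusted p was 0.12. The 22 cholesterol synthesis genes were shifted upward (camera adjusted p = 1.9e-05, 0.82 with an estimated correlation), although only 4 rose and none fell (11 adjusted over the list alone). The calls for HMGCS1 (1.33), LSS (1.09) and MSMO1 (1.0) were lost without any of several single libraries, at limma adjusted p of up to 0.14, 0.076 and 0.12. Of 20 NRF2 targets, 6 fell and none rose (camera adjusted p = 0.00054, 0.62 with an estimated correlation, 6 adjusted over the list alone). They included the aldo-keto reductases AKR1C2, down from 28.7 ± 1.11 to 2.94 ± 1.23 FPKM, and AKR1C3 (log2 fold change −1.69), close paralogs whose reads the quantification may split between them.

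Of 21 interferon response genes, 6 fell and 1 rose in PR1 (camera adjusted p = 0.023, 0.82 with an estimated correlation, 8 adjusted over the list alone). IFI27 fell by 3.03, MX1 by 2.42 and IFI6 by 2.36 on the log2 scale. This list missed the threshold without parental A, without the 3 A libraries and with the filter at 5 FPKM (camera adjusted p = 0.11, 0.14 and 0.13). The list of 24 genes of unfolded protein and amino acid stress was shifted downward (camera adjusted p = 0.040, 0.82 with an estimated correlation), with 1 fall, the lipoprotein receptor gene VLDLR (−1.25), also the only one adjusted over the list alone, and was lost without parental C or PR1 B (camera adjusted p of up to 0.59), at 5 FPKM (0.056) and after quantile normalization (0.095). Among lists that missed the threshold, 4 lineage markers rose, led by MUC5B (3.15), and 2 fell, led by the surfactant gene SFTPB (−3.60). Of 15 mesenchymal markers 5 rose and 4 fell, with VIM at 2.96 and COL6A2 at −1.49. Of 19 MAPK output genes, which the ERK pathway induces, 1 rose and 2 fell, with DUSP6 at −1.21, a call lost without any of several single libraries (limma adjusted p of up to 0.14). None of the 31 cell cycle genes passed limma (0 at an unadjusted p under 0.05), and their median log2 fold change was 0.38. It was 0.64 without parental A and 0.61 without PR1 B.

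With the letter as a block the cell cycle list also passed in PR1, upward (camera adjusted p = 0.022, 0.82 with an estimated correlation), with 2 rises. With the block 3088 genes changed in PR1, and without parental B or PR1 C the count fell to 1166 and 1141. Without the 3 A libraries 2413 genes changed and 1055 changed at least 2-fold, 735 of which were among the 801. Without them 4 more lists passed, cell cycle (3 rises), receptor tyrosine kinases and TGF-beta targets upward and hypoxia and glycolysis downward (camera adjusted p = 0.0077, 0.028, 0.040 and 0.038, and 0.89, 0.46, 0.46 and 0.72 with an estimated correlation).

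PR2 against parental cells asks the same of the second derivative. The leading rises included AXL (5.10), the kallikrein gene KLK5 (log2 fold change 4.45), the matricellular gene THBS1 (4.22), CRIP1 (4.08) and the filamin gene FLNC (4.07). S100P fell from 629 ± 252 to 3.91 ± 1.0 FPKM (SD, n = 3), a log2 fold change of −6.93. The surfactant gene SFTPB fell from 79.6 ± 56.1 to 0.025 ± 0.0085 FPKM, CEACAM5 from 190 ± 59.1 to 1.84 ± 0.71 while CYP2B7P had a log2 fold change of −6.47. BPIFA1 stood at 44.8, 252 and 108 FPKM in the parental libraries and at 0, 0.036 and 0.063 in PR2, and BPIFB1 at 20.2, 125 and 116 against 0, 0.022 and 0.019. In all, 2814 genes changed, 1633 higher and 1181 lower, and 1144 changed at least 2-fold, 649 higher and 495 lower.

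Of 13 measured lung adenocarcinoma lineage markers, 8 fell in PR2 and none rose (camera adjusted p = 1.8e-06, 0.62 with an estimated correlation, 8 adjusted over the list alone). Besides SFTPB and CEACAM5 they included AGR2, which fell from 580 ± 134 to 43.7 ± 16.2 FPKM, and the phosphate transporter gene SLC34A2 (−3.66). Of 19 MAPK output genes, 9 fell and 1 rose (camera adjusted p = 9.6e-06, 0.62 with an estimated correlation, 12 adjusted over the list alone). The ERK phosphatase gene DUSP6 fell from 148 ± 43.3 to 8.86 ± 4.76 FPKM, a log2 fold change of −3.97 ± 0.35. The feedback inhibitor gene SPRY4 had a log2 fold change of −3.02, and the transcription factor genes ETV4 and ETV5 −3.19 and −2.71. SPRED1, counted among the falls, was listed at 0 in the 3 PR2 libraries against 1.92, 7.12 and 2.12 FPKM in parental cells. FOSL1, the member that rose, had a log2 fold change of 1.88, a call lost without any of 4 single libraries (parental B, parental C, PR2 A or PR2 C, limma adjusted p of up to 0.11).

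YAP and TEAD targets rose in 15 of 23 cases and fell in 1 (camera adjusted p = 1.8e-06, 0.62 with an estimated correlation, 17 adjusted over the list alone), with ANKRD1 at 3.21, CYR61 at 2.61 and CRIM1 at 2.45. Of 19 TGF-beta targets, 11 rose and 1 fell (camera adjusted p = 2.4e-05, 0.62 with an estimated correlation, 13 adjusted over the list alone), and the collagen genes COL4A2 (3.49) and COL4A1 (2.89) and ID2 (2.41) were among those that rose. Receptor ligand genes rose in 8 of 16 cases and none fell (camera adjusted p = 0.0037, 0.46 with an estimated correlation, 9 adjusted over the list alone). GAS6, which encodes a ligand of AXL, rose from 2.69 ± 1.13 to 45.7 ± 16.3 FPKM, and was at 15.3 ± 5.69 in PR1 (log2 fold change 2.12). PDGFB (2.48) and NRG1 (2.07) rose as well.

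NRF2 targets fell in 9 of 20 cases and rose in 2 (camera adjusted p = 0.018, 0.82 with an estimated correlation, 11 adjusted over the list alone), led by AKR1C2 (−3.62), AKR1C3 (−2.23) and the glutathione peroxidase gene GPX2 (−1.72). That list was lost without parental C, with the filter at 5 FPKM and after quantile normalization (camera adjusted p = 0.053, 0.064 and 0.078). Ribosomal protein genes fell in 3 of 20 cases (camera adjusted p = 0.0037, 0.82 with an estimated correlation, 3 adjusted over the list alone), with RPS4X at −1.63, and oxidative phosphorylation genes fell in 3 of 25 and rose in 1 (camera adjusted p = 0.034, 0.82 with an estimated correlation, 2 adjusted over the list alone). The ribosomal and oxidative phosphorylation lists did not pass after quantile normalization either (camera adjusted p = 0.30 and 0.39). The first was also lost without PR2 A (camera adjusted p = 0.060) and the second without parental B, PR2 B or PR2 C (camera adjusted p of up to 0.081). Among lists that missed the threshold, 7 mesenchymal markers rose and 2 fell, with FN1 at 3.72, and 7 epithelial markers rose and 3 fell, with the desmosome gene DSP at 1.78. Single members of further lists that missed it also moved, with SOX2 at −3.70, the chemokine gene CXCL8 at −2.43, IL32 at 3.31 and the WNT antagonist gene DKK1 at 3.39.

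Without parental B or PR2 C, 1870 and 1805 genes changed in PR2. Without the 3 A libraries 3389 genes changed and 1443 changed at least 2-fold, 1077 of which were among the 1144. Without them mesenchymal markers passed, with 9 rises and 1 fall (camera adjusted p = 0.00045, 0.59 with an estimated correlation). Interferon genes upward, and hypoxia and stress genes downward, passed too (camera adjusted p = 0.015, 0.037 and 0.0017, and 0.46, 0.72 and 0.72 with an estimated correlation).

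**Figure D3:**
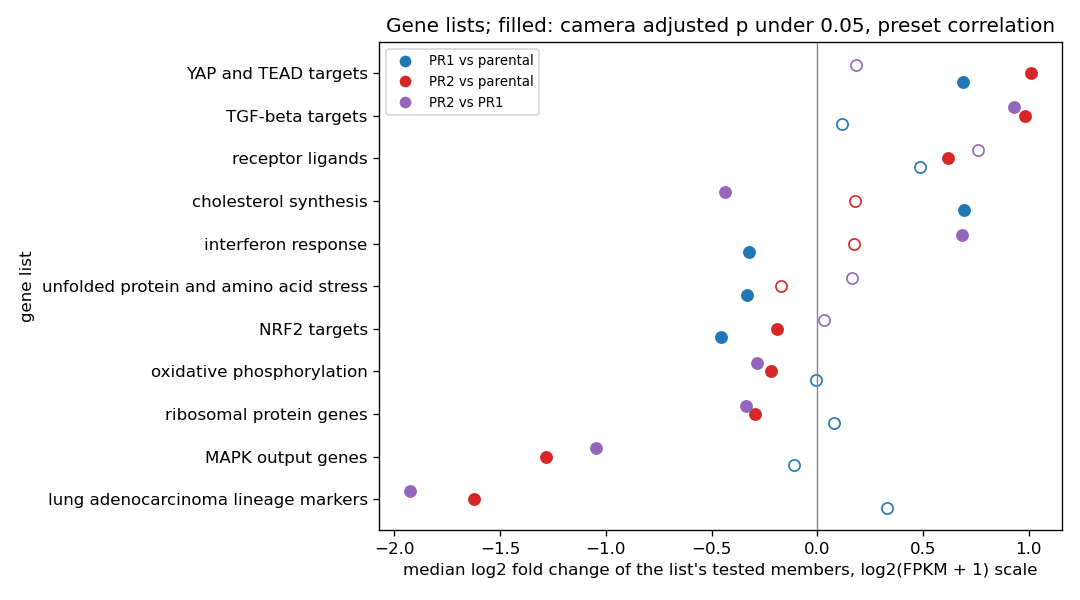
Median log2 fold change, on the log2(FPKM + 1) scale, of the tested members (x axis) of the 11 gene lists (y axis) that passed camera in any comparison, filled where the adjusted p was under 0.05 at the preset correlation. MAPK output genes and lung lineage markers have negative medians in PR2 against both other groups, and YAP and TEAD targets have positive medians in both derivatives.

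Markers of other cell types were low. Of 12 fibroblast markers 3 reached 1 FPKM in at least 3 libraries, the highest value being 10.04 for COL1A1, and of 11 blood cell markers 1 did, CD14, at 9.0 FPKM at most, which fell in PR1 (log2 fold change −1.55) and PR2 (−1.86). Of 16 neuroendocrine markers 2 did, the highest being UCHL1 at 13.5 FPKM, and of 17 cancer testis genes none did.

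The changes of PR1 and PR2 were set side by side. Among genes changed at least 2-fold against parental cells in both, 173 rose and 194 fell in both derivatives, and 26 changed in opposite directions. AXL and CRIP1 were among the shared rises, and CD74, BPIFA1 and SFTPB among the shared falls. Simulated unchanged groups against shared controls gave 0 in each class. Unchanged groups yield almost no calls, so this does not measure what shared controls add to real changes. Independent lists of the same sizes would share 19.7 rises, 18.0 falls and 38.6 opposite changes, though lists with shared controls are not independent. The log2 fold changes correlated across genes at 0.55, inside the range of the simulations (mean 0.50, highest 0.556), in which the parental libraries were shared as well. Their covariance was 0.24 against 0.029 simulated (highest 0.035). The 3 parental libraries are too few to give each derivative at least 2 of its own, so part of the overlap may come from the shared controls. Without the 3 A libraries 473 genes changed in the same and 35 in opposite directions, against 367 and 26. The opposite changes numbered 61 at a pseudocount of 0.1, and 15, 14, 17 and 17 without parental B, PR1 B, PR1 C and PR2 C.

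**Figure D4:**
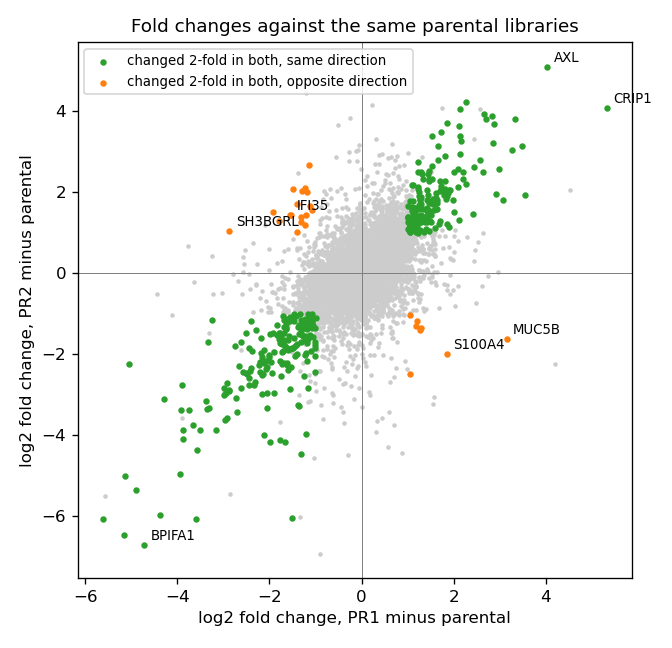
Log2 fold changes of PR1 (x axis) and PR2 (y axis) against the same 3 parental libraries, with 1 point per tested gene (1 gene not drawn). Coloured genes changed at least 2-fold in both, 367 in the same and 26 in opposite directions.

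PR2 against PR1 tests directly whether the derivatives differ. KLK5 was higher in PR2 by a log2 of 5.65 (64.2 ± 19.1 against 0.258 ± 0.014 FPKM, SD, n = 3), and the acetylcholinesterase gene ACHE (4.18), the protease gene ADAMTS1 (4.07), SH3BGRL (3.92) and the histone variant gene H2AFY2 (3.91) were also among the leading differences. S100P was lower by 6.02 (3.91 ± 1.0 against 314 ± 35.1 FPKM), followed by the combined aquaporin locus AQP2,AQP5 (−5.32), TMEM156 (−4.88), the mucin gene MUC5B (−4.77), the chemokine gene CXCL17 (−4.68) and the keratin gene KRT4 (−4.63). In all, 2395 genes differed, 1324 higher and 1071 lower in PR2, and 898 differed at least 2-fold, 493 higher and 405 lower.

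Lung lineage markers were lower in PR2 than in PR1 in 11 of 13 cases and higher in none (camera adjusted p = 2.2e-09, 0.46 with an estimated correlation, 12 adjusted over the list alone). MUC5B, CEACAM5 (−4.54), AGR2 (−4.46) and SLC34A2 (−3.99) led them. MAPK output genes were lower in 12 of 19 cases and higher in none (camera adjusted p = 1.5e-06, 0.62 with an estimated correlation, 12 adjusted over the list alone), with DUSP6 at −2.76, ETV4 at −2.56 and SPRY4 at −2.41. SPRED1 was counted among them and stood at 0.65, 2.35 and 1.42 FPKM in PR1. Interferon response genes were higher in 13 of 21 cases and lower in 2 (camera adjusted p = 4.9e-05, 0.63 with an estimated correlation, 16 adjusted over the list alone), with IFI6 at 3.12, IFI27 at 2.54 and MX1 at 2.03. TGF-beta targets were higher in 8 of 19 cases and lower in 1 (camera adjusted p = 0.00022, 0.62 with an estimated correlation, 11 adjusted over the list alone), and ID2 (2.29) and COL4A1 (2.12) were among those higher.

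Cholesterol synthesis genes were lower in PR2 in 3 of 22 cases, MVK (−1.16) and NSDHL (−0.86) among them (camera adjusted p = 0.0037, 0.82 with an estimated correlation, 3 adjusted over the list alone). Without the 3 A libraries the list was lost (camera adjusted p = 0.088), as was the MVK call (limma adjusted p = 0.066), and the call for NSDHL was lost without PR2 B (limma adjusted p = 0.051). Ribosomal protein genes were lower in 2 of 20 cases (camera adjusted p = 0.0056, 0.82 with an estimated correlation, 2 adjusted over the list alone), with RPS2 at −1.02, and oxidative phosphorylation genes in 2 of 25 (camera adjusted p = 0.047, 0.82 with an estimated correlation, 2 adjusted over the list alone), with NDUFA1 at −1.04. After quantile normalization neither of the last 2 lists passed (camera adjusted p = 0.078 and 0.21), nor without the 3 A libraries (camera adjusted p = 0.055 and 0.092), nor did the first without PR1 B or PR2 A (camera adjusted p of up to 0.079) or the second without parental C, PR1 A, PR2 B or PR2 C (camera adjusted p of up to 0.36).

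With the letter as a block receptor ligands and mesenchymal markers also passed, both upward (camera adjusted p = 0.049 and 0.045, 0.82 with an estimated correlation for each). With the block 3789 genes differed between the derivatives, and without PR1 B, PR2 B or PR2 C the count fell to 1592, 1464 and 1420. Without the 3 A libraries 2384 genes differed and 1031 differed at least 2-fold, 817 of which were among the 898. Without them receptor ligands and mesenchymal markers passed again (camera adjusted p = 0.028 and 0.0023, 0.46 and 0.66 with an estimated correlation).

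Of the lists past camera, some also passed fry, which asks only whether the genes of a list move one way. YAP and TEAD targets (fry adjusted p = 0.0073) and NRF2 targets (0.043) passed in PR1. In PR2 against parental cells lung lineage markers (0.0019), MAPK output genes (0.0073), YAP and TEAD targets (0.0041), TGF-beta targets (0.0041) and receptor ligands (0.0015) passed. Between the derivatives lung lineage markers (0.0015), MAPK output genes (0.0073), interferon genes (0.0087) and TGF-beta targets (0.0097) did, whereas the other lists past camera did not. Among lists that missed camera, receptor tyrosine kinases (fry adjusted p = 0.012), receptor ligands (0.030) and drug transporters (0.024) passed fry upward in PR1. So did receptor tyrosine kinases in PR2 against parental cells (0.0068) and receptor ligands in PR2 against PR1 (0.0073). At the estimated correlation camera passed 0 lists in every comparison, and mixed splits of the same libraries, made within letters where these pair the libraries, passed up to 8, 12 and 9 lists at the preset correlation, against 5, 8 and 7 for the real groups. A mixed split keeps part of the difference between the groups, so its lists are no baseline free of it.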

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

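Of the tests in this part, those of PR2 material in parental A and both tests of the ponatinib dose acting alike were chosen after the result was seen, as was the margin of 1 bootstrap SD asked of every bound.

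ADM, MUC5B, S100A4, SH3BGRL and UCHL1 stood out because they moved in opposite directions in PR1 and PR2, with a difference between the derivatives that passed limma (Benjamini-Hochberg adjusted p from 1.2e-05 for MUC5B to 0.00080 for S100A4). The mucin gene MUC5B rose by 3.15 in PR1 and was at −1.62 in PR2 on the log2 scale, a difference of −4.77, with every PR2 library below every parental one. SH3BGRL was at −2.88 in PR1 and 1.04 in PR2, a difference of 3.92. UCHL1, a neuronal ubiquitin hydrolase gene, was at −1.13 and 1.66, a difference of 2.78, and its call in PR1 was lost without parental C or PR1 C (limma adjusted p of up to 0.067). The adrenomedullin gene ADM was at −0.75 and 1.18, a difference of 1.92. Its call in PR1 lay near the threshold (limma adjusted p = 0.029) and was not followed when libraries were left out. S100A4 was at 1.85 and −2.01, a difference of −3.86, and its call in PR2 was lost without parental A, parental B, PR2 A or PR2 C (limma adjusted p of up to 0.077). Without the 3 A libraries that call was lost as well (limma adjusted p = 0.13), and the S100A4 call in PR1 also lay near the threshold (limma adjusted p = 0.037).

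Libraries of the same letter deviated from their group means together, with a mean correlation across genes between the groups of 0.38 for A, 0.48 for B and 0.14 for C, against −0.16 for libraries of different letters. Deviations cancel within each group, so the last value largely follows from the others and is no separate baseline. The A libraries alone were tested further, and after a trend on transcript length was removed their correlation was 0.406 ± 0.021 (bootstrap SD over genes), against 0.370 before. For GC content it was 0.396 ± 0.021, and among genes at 20 FPKM or more, where counting error is small, it was 0.404 ± 0.038. These values lie above the bound of 0.2 by more than 2 SDs, against length, GC content and the counting error of low genes as the whole source. Each A library was the deepest of its group (relative depth 1 in parental cells, 0.983 in PR1 and 0.941 in PR2). Other effects that go with depth therefore cannot be told apart from the letter. What the A libraries share, such as a day of culture or of library preparation, is not given in the labels and stays open, and no biological explanation was tested.

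Parental A lay toward the derivatives, with its difference from parental B or C following the PR2 effect at a slope of 0.19. If PR2 cells or RNA were mixed into it, the 41 genes that were far higher in PR2 put the share at a median of 5.03% (quartiles 3.47% and 13.6%), which allows a median log2 ratio of −0.074 for the 777 genes lower in PR2. The ratio was −0.344 ± 0.025, below the bound of −0.3 by 1 SD but not by the 2 SDs first applied. The test was also rewritten after a first value was seen, because that version chose genes on the libraries it compared. An effect common to the A libraries left 0.687 ± 0.053 of the slope once the deviation of PR1 A was subtracted, above the bound of 0.5. That subtraction takes the effect to be equally large in parental A and PR1 A, and the mixing test covers PR2 material only. The values argue against an A effect of equal size alone as the source of the whole slope. For PR2 material alone the mixing test does not decide, since its bound was passed only at the margin chosen later. PR2 material, a larger A effect in parental A, a state of the parental culture that differed at A, or several of these together may remain. Apart from the mixing test, none of these was tested.

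MAPK output genes were lower in PR2 than in parental cells, with a median log2 fold change of −1.28 over 19 genes. After the trend on transcript length and GC content was removed, the median was −1.15 ± 0.43 (bootstrap SD over genes), below the bound of −0.5 by 1 SD but not by the 2 SDs first applied, against that trend as the whole source. The labelled ponatinib dose acting alike on both derivatives would need a like fall in PR1, where the median was −0.11 ± 0.20, above −0.5 by 1 SD and just short of 2. It would also leave no difference between the derivatives, but 12 of the 19 genes were lower in PR2 than in PR1 and none higher (fry adjusted p = 0.0073, camera adjusted p = 0.62 with an estimated correlation), with a median of −1.045 ± 0.33, below −0.5 by 1 SD but not by 2. That median uses the same PR1 and PR2 values and is not separate evidence. Both tests of the dose were written after these values were seen, so their outcome was known and they do not decide the question. The SDs treat genes as independent, although the list's estimated correlation was 0.33, and leave out the spread between libraries, so they are too small. What set the derivatives apart, whether the lines that the design names or their histories in culture, was not tested and stays open.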

How the results depend on the processing

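The fit without the 3 A libraries was chosen after the data were seen, and the other alternatives were fixed before. With the filter at 5 FPKM, 1207 (PR1 against parental), 1811 (PR2 against parental) and 1573 (PR2 against PR1) genes changed, and 532, 750 and 598 did so at least 2-fold, with fewer genes tested. The test against a 2-fold change left 99 (33 higher and 66 lower), 267 (120 and 147) and 144 (73 and 71), so that in PR2 against parental most were lower, unlike the 649 higher and 495 lower of the main fit. With the replicate letter as a block the counts were 3088 for PR1 against parental and 3789 for PR2 against PR1, and 4113 for PR2 against parental, where the letters did not pair the libraries although each of the 9 libraries correlated best with its own letter. Without a filter the share of changed genes that were higher in PR1 was 39.0% in place of 48.7%. Without the 3 A libraries 8, 12 and 6 lists passed, against 5, 8 and 7, and with the block 6, 10 and 9. The estimated correlation left 0, 0 and 0 lists past camera, with 5, 6 and 5 past fry and 0, 3 and 2 past an unadjusted p of 0.05. Genes changed in opposite directions numbered 61 at a pseudocount of 0.1. Except for the fewer genes tested at 5 FPKM, the cause was not tested.

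Leaving out 1 library at a time gave 1141 to 2027 changed genes for PR1 against parental, 1805 to 2922 for PR2 against parental and 1420 to 2446 for PR2 against PR1. The lists past camera numbered 4 to 8, 7 to 10 and 6 to 8, and the opposite changes 14 to 28. None of the named genes' calls changed direction under the alternatives run, and no list past camera passed in the other direction, although the median of the unfolded protein and amino acid stress list in PR1 was 0.019 without parental C. Of the 192 gene results, 34 lost their call under at least 1 setting and 5 gained one, and 15 lost it under a setting that kept all libraries, 14 of them without a filter, among them CTGF, HMGCS1, MSMO1 and DUSP6 in PR1, FOSL1 in PR2 and RPS2 between the derivatives. The block ended no call among them and gave 4, for AXL and EGFR between the derivatives and for HRAS in PR2 against both other groups. Between PR2 and PR1, AXL also passed after quantile normalization and with only the 6 libraries compared (limma adjusted p = 0.046 and 0.032), and EGFR with median-of-ratios scaling and quantile normalization (limma adjusted p = 0.047 and 0.030). Of the 20 lists past camera, 9 were lost with fry, 6 after quantile normalization and 7 without 1 library. The oxidative phosphorylation list in PR2 against PR1 was also lost at a pseudocount of 0.1 and with the filter at 5 FPKM (camera adjusted p = 0.051 and 0.064). Lists that missed the threshold also passed under some settings. Mesenchymal markers in PR2 against parental passed after quantile normalization, with the block and without any of several single libraries (camera adjusted p = 0.049, 0.044 and down to 0.0084). At an estimated correlation the camera adjusted p was 0.84 after quantile normalization, 0.82 with the block and 0.78 without parental A. The cell cycle list in PR1 passed without parental A or PR1 B (camera adjusted p = 0.0012 for each). With the filter at 5 FPKM, WNT and NOTCH targets passed in PR1 and hypoxia and glycolysis in PR2 against parental (camera adjusted p = 0.0052 and 0.035).

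PR2 against parental has 10 splits of its 6 libraries, so no share under 0.1 was possible. Where the letters pair the libraries, in PR1 against parental and PR2 against PR1, only the 4 splits within letters were used, a choice made after the data were seen, so no share under 0.25 was possible. The real split gave 1866 (PR1 against parental), 2814 (PR2 against parental) and 2395 (PR2 against PR1) changed genes (2-fold 801, 1144 and 898). Others gave at most 0, 1 and 0 for both. Mixed splits carry the group difference as spread, which limits calls, so splits cannot exclude chance in any comparison. For gene lists 4 of 4, 6 of 10 and 4 of 4 splits gave as many, with 5, 8 and 7 real lists against up to 8, 12 and 9. With the block 2 of 4 splits gave as many in PR1 against parental and in PR2 against PR1, so the number of lists past camera does not mark out the real groups. Absolute depth is unknown, and changes of genes near 1 FPKM are limited by it.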

Other observations

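The genes and loci in this part were chosen after their values were seen, and no explanation was tested for them.

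Antigen presentation genes moved apart in the derivatives. The combined class I locus HLA-B,HLA-C stood at 637 ± 75.9 FPKM in parental cells (SD, n = 3), fell to 370 ± 20.6 in PR1 and rose to 1697 ± 328 in PR2 (log2 fold change −0.78 and 1.40, limma adjusted p = 0.018 and 0.00051). B2M, the class I light chain, rose from 884 ± 43.4 to 2405 ± 751 FPKM in PR2, and the class I activator gene NLRC5 from 2.02 ± 0.22 to 6.28 ± 1.93. In PR1 both missed the threshold (limma adjusted p = 0.16 and 0.32). The class II locus HLA-DRB1,HLA-DRB5 went the other way in PR2 and fell in both derivatives, from 24.8 ± 7.60 to 1.23 ± 0.88 FPKM in PR1 and 0.219 ± 0.14 in PR2. The interferon-induced gene IFI35 fell from 8.38 ± 0.22 to 2.2 ± 0.16 FPKM in PR1 and rose to 24.3 ± 2.46 in PR2. HLA genes are near-identical copies that differ between genomes, several are listed at 0 in every library, and the combined loci cannot be split.

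Of the kallikrein genes, which encode secreted proteases, 6 rows were tested one by one. In PR1 4 rows fell and none rose, among them KLK10, from 72.4 ± 45.5 to 4.58 ± 3.97 FPKM (SD, n = 3), and KLK6, from 23.5 ± 18.1 to 2.56 ± 0.39. In PR2 KLK10 was at 51.8 ± 12.8 and KLK6 at 27.0 ± 14.9 FPKM, and only KLK5 rose, while the locus KLK11,KLK12 and KLK13 fell in both derivatives. Against PR1, 4 rows were higher in PR2 and none lower, while KLK11,KLK12 and KLK13 missed the threshold (limma adjusted p = 0.75 and 0.76).

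At 0 in all libraries of a derivative and at 1 FPKM or more in every parental library were 6 rows in PR1 and 13 in PR2. SOX21, a transcription factor gene, was listed at 0 in the 6 derivative libraries and at 8.03, 11.4 and 7.82 FPKM in the parental ones. ACER3, a ceramidase gene, was listed at 0 in PR2 but at 2.10, 3.13 and 2.66 FPKM in PR1 and 3.59, 3.41 and 3.71 in parental cells. SPRED1, also listed at 0 in PR2, has FAM98B as a neighbour in the GRCh38.p14 annotation, which stood at 8.68, 6.51 and 7.57 FPKM in the same libraries.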
